A study of Mus musculus with 23 samples.

How the data were processed

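The 23 arrays measured RNA of separated epithelium and mesenchyme of the lacrimal gland (LG), the harderian gland (HG) and the eyelid at embryonic day 16.5 (6 groups of 3 arrays), and of whole LG (2 arrays) and whole HG (3 arrays) at 7 weeks. Each group was taken from the submitters' labels. Per the file headers, the arrays were 1-colour (Cy3) Agilent mouse arrays of 1 design, on 3 slides. Slide 1 held replicate 1 of every embryonic group and adult HG replicate 1. Slides 2 and 3 held replicates 2 and 3, with adult LG replicates 1 and 2, so slide equals replicate number except in adult LG.

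The deposited scanner files give intensity per spot on a linear scale, background-subtracted and detrended within each array by the authors' scanner software (gProcessedSignal), with raw spot and background medians and 0 or 1 flags. Per the submitters' processing notes the software was Agilent Feature Extraction 11.5.1.1, whereas per the file headers slide 1 was read with 11.0.1.1 and a different protocol version. The deposited series matrix also holds intensity on a linear scale. Its values matched the mean gProcessedSignal over the spots of each probe on all 23 arrays (median log2 ratio 0, with an SD over probes of 0.0369 at most), so the authors' matrix was not scaled between arrays. Each array had 59305 spots apart from controls, none of them saturated, and 109 to 187 outlier spots by the flags for uneven or outlying pixels.

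Outlier spots were left out, which left 32 values missing, and spots of a probe were averaged. The value used was log2 of gProcessedSignal minus the array's 75th percentile. Names came from the RefSeq accession in each probe's systematic name, matched without version to a table of accessions and symbols. Of 55681 probes 27509 matched 20887 symbols, and 28172 matched none and were not used here except in 1 alternative. A probe was kept when at least a 0.5 share of its spots was well above background on every array of at least 1 group, and the probe with the highest mean stood for its gene, which left 16324 genes. Signal over background sets the precision here. On the adult LG arrays 50.3 and 42.4 percent of spots were well above background, fewer than on most others, so low transcripts of that group are known least well.

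All 23 arrays and 8 groups entered 1 fit with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the data.table package (version 1.17.8) for reading and matplotlib 3.10.9 for figures. Each comparison was a contrast of group means, tested by limma's moderated test, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Counts at least 2-fold were taken beside it. A moderated F test asked whether the difference between epithelium and mesenchyme depended on the tissue, and a difference of differences asked the same of LG against HG by age. The LG epithelium set took genes called at least 2-fold higher in LG epithelium in 3 comparisons. Because the replicate numbers might pair the embryonic samples, the residuals of arrays with the same number were correlated across genes. Every such pair exceeded 0.1 in the 9 embryonic comparisons (0.171 to 0.579), but not every pair did in comparisons with adult glands, where the lowest was -0.341. The pairing comes from the labels' replicate number, which for embryonic arrays is also the slide, so slide and pair cannot be told apart. Both were tried as a block.

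The lists fixed before the data were examined, as were the groups, tests, alternatives and the rule for naming genes, held markers or members of the following: epithelium, mesenchyme, endothelium, immune cells, erythroid cells, skeletal muscle, neurons, Schwann cells and melanocytes, adipocytes, cartilage and bone, lens with retina and pigment epithelium, conjunctiva and cornea, epidermal differentiation, hair placode and follicle, periocular mesenchyme factors, gland development regulators, lacrimal secretion, lipid synthesis, porphyrin synthesis, secretory machinery of the endoplasmic reticulum, cell cycle, retinoic acid pathway, sex-linked genes, and the responses to FGF, Wnt, BMP and hedgehog signalling. Of these 27 lists 26 had at least 5 measured genes and were tested with limma's camera, at a preset correlation of 0.01 and at an estimated correlation, adjusted over lists within a comparison. Members called were counted over all genes and adjusted over the list alone.

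Named genes were up to 10 with the largest and 10 with the smallest log2 difference for epithelium against mesenchyme over 3 tissues, LG against HG epithelium, LG against eyelid epithelium and adult LG against adult HG, and 5 and 5 for the other comparisons. All were called, well above background on every array of the brighter group and without overlap between groups; the last 2 conditions did not apply to differences of differences. For the F test the 5 largest F values were named, for the LG epithelium set the 20 largest by the smallest of 3 differences, and for each list and comparison up to 4 called members. Symbols of predicted or unnamed genes were passed over. Pax6, Foxc1, Fgf10, Fgfr2, Sox9, Sox10 and Barx2 were among the genes always examined. Some genes that these rules name are not reported here, but are tested and counted with the others. Members of the sex-linked list, and members of the cartilage and Wnt response lists used to test an explanation, are named beyond this rule.

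The procedure was tested on simulated data with 16324 genes and each gene's own spread in the fit. For true log2 differences of 1 and 2 it recovered 48 and 84 percent of changed genes in LG against HG epithelium, 56 and 85 in LG epithelium against mesenchyme, 57 and 88 in the HG, 48 and 88 in the eyelid, 56 and 90 in LG against eyelid epithelium, 48 and 85 in HG against eyelid epithelium, 51 and 91, 57 and 89, and 56 and 87 in the mesenchymes (LG against HG, LG against eyelid, HG against eyelid). It recovered 45 and 80 in adult LG against HG, 39 and 78 in adult against embryonic LG, 46 and 87 in adult against embryonic HG, 86 and 100 for epithelium against mesenchyme over 3 tissues, 19 and 84 for the F test and 18 and 76 for the difference by age. Unchanged genes called numbered 3 to 16. The LG epithelium set recovered 72 and 88 percent at 1.5 and 2.5, with 0 unchanged genes. Of 26 lists the 3 shifted by 0.7 were called, and 0 others. The simulated noise was independent between genes and arrays, so this does not test list calls where the genes of a list are correlated.

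Alternatives changed 1 choice at a time, except that normexp came together with quantile normalization: normexp background correction with offset 50 followed by quantile normalization, quantile normalization alone, median scaling, no filter on dim probes, a filter for probes well above background on all 23 arrays, outlier spots kept, the mean over the probes of a gene, eBayes with trend and robust, slide or replicate number as a block, the series matrix, leaving out slide 1, only the compared groups, a 2-fold threshold, an estimated correlation, and leaving out each array in turn. Normexp used the median spot signal, since the mean spot signal is not among the columns used here. No coordinates are given, since the headers' genome build differs from that of the symbol table.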

Results

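The arrays profiled gene expression in the glands and the skin around the mouse eye. At embryonic day 16.5 the lacrimal gland (LG), the harderian gland (HG) and the eyelid, with the conjunctiva that lines it, were each separated into epithelium and mesenchyme, with 3 arrays per group. Whole LG (2 arrays) and whole HG (3 arrays) were taken from mice at 7 weeks. The LG makes the watery, protein-rich part of the tear fluid, whereas the HG is a lipid-secreting gland of the orbit. Between 42.4 and 64.6 percent of the spots on an array were well above background, and the adult LG arrays had the lowest 75th-percentile signals, 194 and 139 intensity units, against 313 to 857 on the other 21 arrays. The 20 brightest probes carried 8.14 and 9.16 percent of the signal on the adult LG arrays and at most 4.60 percent elsewhere. The number of arrays per group limits the precision of every difference. The p-values measure only the spread between these arrays, because the labels do not say whether each array came from separate animals. All differences below are log2 values with their standard error (SE), higher meaning higher in the group named earlier in the comparison.

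Arrays of the same group lay close together. The largest component of variance (38.0 percent) parted whole adult glands from separated embryonic tissue, and the next (25.5 percent) parted epithelium from mesenchyme. The third component (12.7 percent) set both eyelid compartments apart from the embryonic glands, the epithelium most, and the fourth (9.70 percent) parted adult LG from adult HG. The lowest correlation between arrays of a group across genes was 0.985 to 0.990 in the embryonic groups, 0.971 in adult LG and 0.959 in adult HG. Genes are not independent replicates, so these values describe only how alike the arrays were.

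**Figure D1:**
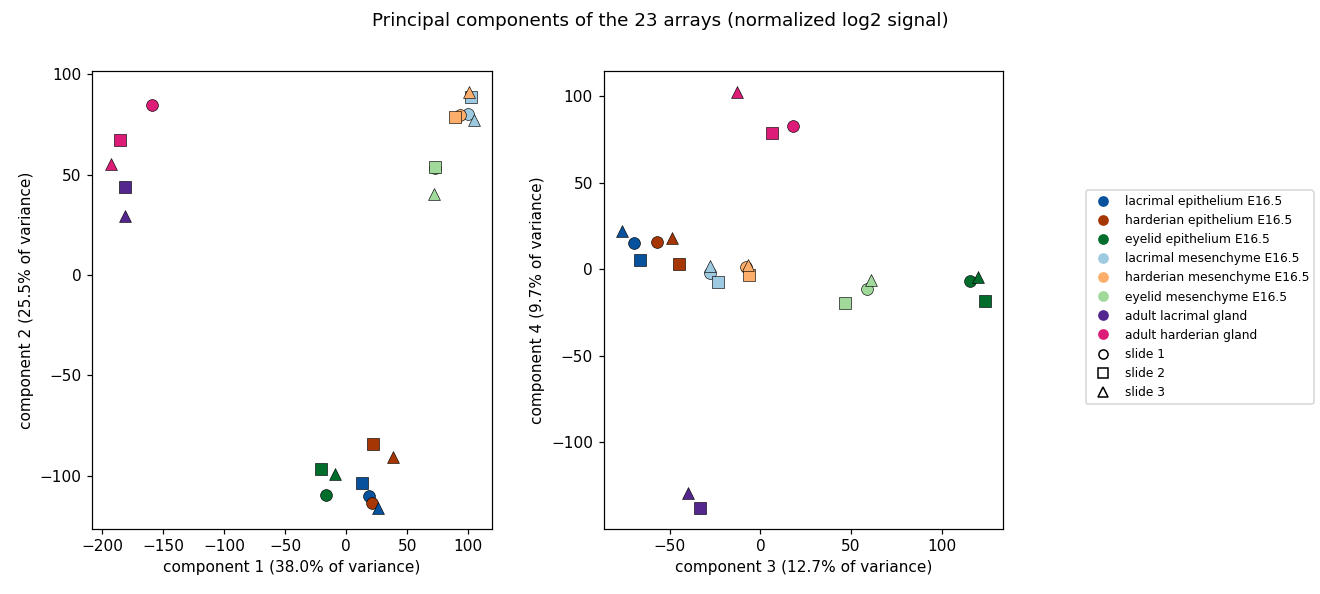
Principal components of the 23 arrays, with component 1 against 2 and component 3 against 4 (arbitrary units; percent of variance on each axis); colours mark the 8 groups and shapes the 3 slides. Adult arrays separate from embryonic arrays on component 1, epithelium separates from mesenchyme on component 2, and the adult glands part on component 4, with adult LG at -138 and -129.

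The broadest question was which genes separate epithelium from mesenchyme in the mean of LG, HG and eyelid (9 arrays against 9). Pax6, the transcription factor needed for eye and ocular gland development, was higher in epithelium by 4.65 ± 0.27 (adjusted p = 2.81e-11). Foxc1 was higher by 3.50 ± 0.18, the neural crest and gland factor Sox10 by 3.06 ± 0.17, and Sox9 by 1.90 ± 0.14. Fgf10, the growth factor secreted by mesenchyme that induces lacrimal buds, had the lowest difference of the comparison's named genes, -5.67 ± 0.41 (adjusted p = 4.78e-10; -5.65, -6.03 and -5.33 within slides 1, 2 and 3). Its receptor gene Fgfr2 was higher in epithelium by 0.87 ± 0.06 and Barx2 by 1.90 ± 0.28. Pax6 and Foxc1 may have been chosen for study from these same samples, so their values here are not independent evidence.

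The largest differences on the epithelial side belonged to Prom2 (5.91), Aadac (5.51), Ano9 (5.50), Krt23 (5.47), the clathrin adaptor gene Ap1m2 (5.29), Lad1 (5.21), the desmosome gene Dsp (5.20), Urah (5.17), and Otx1 and Atp6v1c2 (both 5.11). A further Prom2 probe gave 3.01. On the mesenchymal side stood, after Fgf10, Akr1c14 (-5.63), the Wnt co-activator Rspo2 (-5.57), Grm7 (-5.57), B3galt1 (-5.46), Rbp4 (-5.43), the chemokine Cxcl12 (-5.35) and Hoxd8 (-5.29). Klhl4 was at least 12.3-fold lower in epithelium (adjusted p = 3.23e-12). Such bounds are used where no probe of a gene was well above background on any array of the dimmer group. Where only some arrays or probes were below it, the fitted difference is given, and its size is uncertain. The bounds set the mean of the brighter group against the mean of the higher of the dimmest clearly measured signal and the probe's own signal on each array of the dimmer group.

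Every one of the 45 measured epithelial genes rose and all 35 mesenchymal genes fell, with median differences of 4.38 and -4.15 (adjusted p = 4.95e-17 for each list and adjusted p = 0.181 with an estimated correlation for both). Within slides 1 to 3 the medians were 4.39, 4.28 and 4.50 for the epithelial list and -4.61, -3.95 and -3.84 for the mesenchymal list. Cldn4 (5.10), Cldn6 (5.08), Prrx1 (-4.84), Cdh11 (-4.82) and Lum (-4.75) were examples. Cell types that live in connective tissue went with the mesenchyme. Of 17 endothelial genes 16 were lower (Cdh5 -4.42, Emcn -4.39; adjusted p = 3.37e-09 and adjusted p = 0.194 with an estimated correlation). Of 25 immune genes 19 were lower and 1 higher (Tyrobp -4.16), and of 25 skeletal muscle genes 22 were lower and 1 higher (Des -4.54), 23 lower when adjusted over the list alone. All 11 erythroid genes were lower (Hbb-y -4.11). For these lists the tests gave adjusted p = 1.89e-05, 0.000245 and 0.000686, and adjusted p = 0.318, 0.409 and 0.23 with an estimated correlation. Of 12 neuronal genes 7 were lower and 1 higher (Nefl -4.19; adjusted p = 0.0243 and adjusted p = 0.307 with an estimated correlation). Of 14 Schwann cell and melanocyte genes 9 were lower and 2 higher, 10 lower when adjusted over the list alone (S100b -4.66, Dct -3.31; adjusted p = 0.0137 and adjusted p = 0.23 with an estimated correlation). Counts adjusted over the list alone equalled those over all genes wherever no other count is given.

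Signalling targets also divided between the compartments. Of 15 genes that respond to FGF signalling, 11 were higher in epithelium and 1 lower, with Shisa2 at 2.54, the ETS factor Etv4 at 2.46 and the phosphatase Dusp4 at 2.10 (median 1.21, adjusted p = 0.00342 and adjusted p = 0.23 with an estimated correlation). Hedgehog response genes went the other way, 7 of 9 lower and 2 higher (Hhip -3.57, Gli1 -2.44; adjusted p = 0.0181 and adjusted p = 0.181 with an estimated correlation). Of 27 regulators of gland development 18 were higher and 6 lower (Elf5 4.88; adjusted p = 0.00342 and adjusted p = 0.238 with an estimated correlation), a list that holds Pax6 and Foxc1 and is no independent evidence for them. Periocular mesenchyme factors were lower for 16 of 28 and higher for 5 (Alx1 -4.73, Osr1 -4.57; adjusted p = 0.00829 and adjusted p = 0.318 with an estimated correlation). Cell cycle genes were slightly higher in epithelium, 23 of 30 with 1 lower (Plk1 1.02, Cdc20 0.99; median 0.63, adjusted p = 0.00228 and adjusted p = 0.318 with an estimated correlation). In all, 6311 genes were higher and 5216 lower in epithelium (2305 and 3073 at least 2-fold), and 6871 and 5596 with slide as a block.

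The next question was whether each tissue divided in the same way. In the LG (3 arrays against 3) Pax6 (5.63 ± 0.47), Sox10 (5.18 ± 0.29) and Foxc1 (5.12 ± 0.32) were higher in epithelium, and Fgf10 was lower (-5.79 ± 0.71). FGF response genes were higher for 10 of 15 and lower for 1, 11 and 1 when adjusted over the list alone (Shisa2 4.56 ± 0.20, Phlda1 3.56, Il17rd 2.96). Their median was 2.52, with 2.25, 2.72 and 2.63 within slides (adjusted p = 0.000309 and adjusted p = 0.214 with an estimated correlation). Prom2 (6.91) led the epithelial side, with Serpinb5 at least 38.5-fold, Rgr at least 31.2-fold, Otx1 at least 27.2-fold and Slain1 at least 26.7-fold higher (adjusted p at most 3.36e-08). Rspo2 (-6.53), Neto1 (-6.34), Akr1c14 (-6.30) and Pcdh9 (-6.29) led the mesenchymal side, and Sucnr1 was at least 31.8-fold lower (adjusted p = 5.48e-09). The other probes of Pcdh9 also gave lower values, -2.96 for the lowest. The cartilage collagen genes Col2a1 (5.88 ± 0.54) and Col9a1 (5.87 ± 0.70) were also higher in LG epithelium, although the second Col9a1 probe gave -0.30. In total 5235 genes were higher and 4334 lower (5899 and 4784 with slide as a block, but 2664 and 3179 at least 2-fold), and the median over all genes was 0.11.

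In the HG (3 against 3) the epithelium was richer in cell cycle transcripts, with 28 of 30 genes higher and none lower (Aurka 1.79, Rrm2 1.75; median 1.35, adjusted p = 1e-07 and adjusted p = 0.152 with an estimated correlation). Wnt response genes were higher for 10 of 15 and lower for 2. The Wnt feedback ligase gene Rnf43 (5.18), Tnfrsf19 (4.69) and Tcf7 (3.99) were among the higher ones, and Dkk2 was lower (-3.99; list adjusted p = 0.01 and adjusted p = 0.21 with an estimated correlation). Genes of hair placodes and follicles were higher for 12 of 21 (Dkk4 5.28, Wnt10a 4.76, Edar at least 14.7-fold; adjusted p = 0.000744 and adjusted p = 0.0662 with an estimated correlation). Pigment cell genes marked the HG mesenchyme, with Tyrp1 at -5.88, Dct at -5.60 and Pmel at -5.12, and 10 of 14 genes of the Schwann cell and melanocyte list lower with 3 higher (adjusted p = 0.00321 and adjusted p = 0.152 with an estimated correlation). FGF response genes were higher for 11 of 15 (Etv4 4.57, Dusp6 2.88; adjusted p = 0.000231 and adjusted p = 0.152 with an estimated correlation). Htr7 (-7.43 ± 0.70), Fgf10 (-6.74), Brinp3 (-6.57), Akr1c19 (-6.48) and Wdr72 (-6.39, but 0.08 with its other probe) were the lowest. Cldn6 (6.12), Lad1 (5.92), Syne1 (5.89, but 0.25 with its other probe), Prom2 (5.88) and Ap1m2 (5.87) were the highest. Pax6 (5.19), Sox10 (3.84) and Foxc1 (2.71) were higher. Here 4861 genes were higher and 4586 lower (5483 and 5136 with slide as a block, but 2698 and 3290 at least 2-fold).

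The eyelid (3 against 3) showed a keratinizing epithelium over a muscle-bearing mesenchyme. Of 39 epidermal differentiation genes 37 were higher in epithelium, 38 when adjusted over the list alone (Sprr3 6.22, Krt77 6.16, Dsc1 6.11, Sprr2d at least 25.1-fold). Their median was 4.76, with 4.59, 5.46 and 4.28 within slides (adjusted p = 4.24e-18 and adjusted p = 0.0227 with an estimated correlation). Of 25 skeletal muscle genes 23 were lower (Myl1 -6.26, Tnnt3 -6.21, Myh3 -6.19; median -5.21, adjusted p = 4.87e-08 and adjusted p = 0.385 with an estimated correlation). Cartilage and bone genes were lower for 10 of 12 and higher for 1 (Ibsp -4.89, Col9a2 -4.56; adjusted p = 0.00257 and adjusted p = 0.0614 with an estimated correlation). Lipid synthesis genes were higher for 20 of 42 and lower for 8 (adjusted p = 0.0471 and adjusted p = 0.467 with an estimated correlation), a call that ended with slide as a block (adjusted p = 0.0604). Orm2 (7.02) was the highest gene, with Pla2g4f at least 53.2-fold, Upk3b at least 35.1-fold and Lipk at least 21.0-fold higher (adjusted p at most 2.34e-07). Rbp4 (-6.66), Dpt (-6.60), Aspn (-6.44), Cav3 (-6.41) and Ecrg4 (-6.30) were the lowest. Sox10 did not pass (0.15, adjusted p = 0.695). There were 4189 genes higher and 4165 lower (4968 and 4671 with slide as a block, but 2296 and 2952 at least 2-fold).

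The F test for a tissue-dependent difference between epithelium and mesenchyme, on all 3 tissues, called 6905 genes (8522 with slide as a block, 3953 with median scaling). Sox10 (F = 81.6), Foxc1 (F = 19.7), Sox9 (F = 15.8), Pax6 (F = 8.03) and Fgfr2 (F = 5.49) were among them, whereas Fgf10 (adjusted p = 0.185) and Barx2 (adjusted p = 0.193) were not. The largest F values were those of Sprr2d, Limch1, Lmo7, Dnase1l2 and Sbsn. The actin-binding gene Limch1 was higher in gland epithelium (1.01 in LG, 1.30 in HG) and lower in eyelid epithelium (-3.73). Lmo7 did the opposite (-2.23, -1.74 and 2.32).

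**Figure D2:**
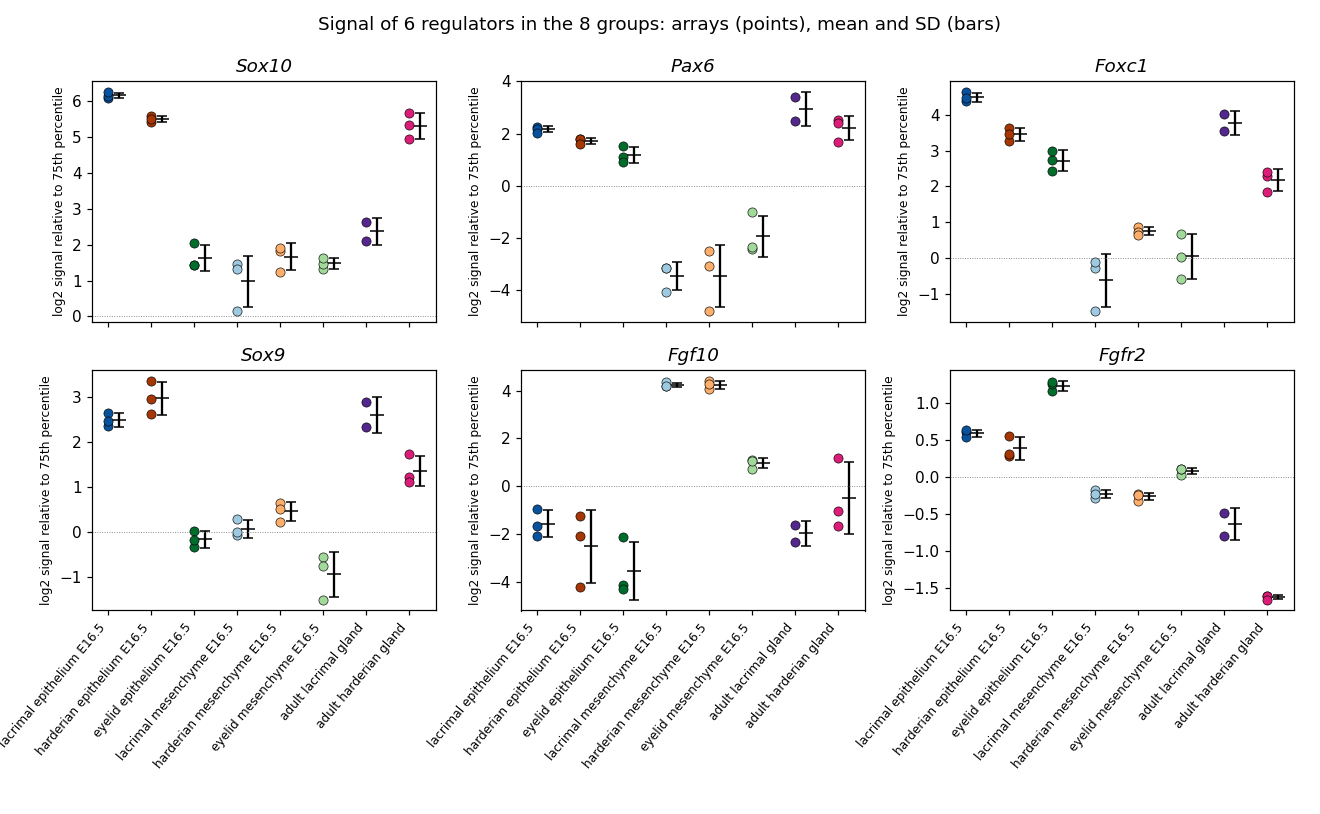
Level of 6 regulators (log2 signal minus the array's 75th percentile) in each of the 8 groups; points are single arrays, bars the group mean with its standard deviation (SD). Fgf10 is at 4.23 in LG mesenchyme and 4.24 in HG mesenchyme.

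The comparison of LG epithelium with HG epithelium (3 arrays against 3) asked what sets apart both gland epithelia at the same stage. The homeobox gene Six2 was higher in LG epithelium by 3.59 ± 0.44. The secreted protein gene Crispld2 (4.25 ± 0.36), the integrin gene Itga4 (4.29), Otor, the neurotrophin receptor gene Ntrk3 (3.92) and Xdh (3.85) were also higher. Fam163a was at least 18.4-fold, Lgsn at least 11.6-fold, the muscarinic receptor gene Chrm3 at least 9.48-fold and Rag1 at least 8.28-fold higher (adjusted p at most 2.15e-05), although the second Rag1 probe gave -0.02. The water channel gene Aqp5 of lacrimal acinar cells was higher by 2.31 ± 0.30. Foxc1 missed the threshold (1.04, adjusted p = 0.0621) but passed with slide as a block (adjusted p = 0.00768), with 1.11 and 1.01 within slides 2 and 3. Pax6 (0.43, adjusted p = 0.875), Sox10 (0.65, adjusted p = 0.272) and Sox9 (-0.48, adjusted p = 0.394) did not pass. Within slides 1 to 3 Pax6 was higher by 0.46, 0.40 and 0.44 and Sox10 by 0.50, 0.71 and 0.75, without overlap between groups. Sox9 overlapped. The fit takes the spread of each gene over all 8 groups, so missing the threshold does not show equal levels.

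Genes of the Wnt response were lower in LG epithelium. The Wnt transcription factor gene Lef1 (-5.67 ± 0.41, adjusted p = 5.89e-08) and Sp5 (-5.52 ± 0.37) were among the lowest genes of the comparison, as was Dkk4 of the hair placode list (-6.73 ± 0.50, adjusted p = 7.91e-08). Lef1 was at -5.39, -5.96 and -5.65 within slides, with an adjusted p of 2.01e-07 with slide as a block. Of 15 Wnt response genes 8 were lower and 1 higher, 11 and 2 when adjusted over the list alone (Lgr5 -3.87, Wif1 -3.16; median -1.94). The list passed with the preset correlation (adjusted p = 4.69e-11), with an estimated one (adjusted p = 0.00319) and with slide as a block (adjusted p = 8.82e-10), at medians of -1.61, -1.98 and -1.74 within slides. Of 21 hair placode and follicle genes 5 were lower, 6 when adjusted over the list alone (adjusted p = 1.42e-06 and adjusted p = 0.00319 with an estimated correlation), and Lef1, Lgr5 and other members stand on both lists. BMP response genes were lower for 3 of 10, 5 when adjusted over the list alone (Id1 -2.71, Id3 -2.67; adjusted p = 0.000486 and adjusted p = 0.0432 with an estimated correlation). Gata6 (-6.25 ± 0.48), Cdh13 (-4.61), Serpinb11 (at least 21.0-fold), Ccn6 (at least 8.76-fold), Me3 (at least 8.19-fold, -3.51 and -0.44 with its other probes), Mep1a (at least 8.09-fold) and Wt1 (at least 7.86-fold) were lower as well. The ligand gene Bmp4 was lower by one probe (-2.69) and at -0.17 by the other.

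Markers of other cells moved with the HG epithelium. Of 35 mesenchymal genes 10 were lower in LG epithelium and 1 higher, 14 and 1 when adjusted over the list alone (Dpt -3.50, Meox1 -2.56, Lox -1.82). The list median was -0.72, but 0.02, -0.86 and -0.97 within slides (adjusted p = 4.66e-08 and adjusted p = 0.602 with an estimated correlation). Pigment cell genes were lower, with Dct at -4.39 and Tyrp1 at least 5.98-fold, 3 of 14 of their list lower and 1 higher, 5 lower when adjusted over the list alone (adjusted p = 0.00176 and adjusted p = 0.163 with an estimated correlation). Of 17 endothelial genes 1 was lower (Ramp2 -1.62; adjusted p = 5.14e-05 and adjusted p = 0.602 with an estimated correlation). Of 25 muscle genes 1 was lower (Myog, at least 2.63-fold on average but not lower on slide 1; list adjusted p = 0.032 and adjusted p = 0.831 with an estimated correlation), a list call that ended with slide as a block (adjusted p = 0.0628). Lipid synthesis genes were higher for 5 of 42 in LG epithelium, 9 with 1 lower when adjusted over the list alone (Mogat1 1.67, Scd1 1.45; adjusted p = 0.0163 and adjusted p = 0.65 with an estimated correlation). In total 484 genes were higher and 553 lower (313 and 451 at least 2-fold), and 634 and 653 with slide as a block. Without slide 1 there were 280 and 545, with median scaling 258 and 372. The balance turned among probes well above background on all 23 arrays (288 and 228). It also turned with normexp and quantile normalization together (549 and 527) and in a fit of only these groups (556 and 524). Without the genes at least 4-fold higher in the other compartment, an alternative chosen after seeing the data, there were 400 and 260.

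Against eyelid epithelium (3 against 3), LG epithelium was far lower in genes of the forming skin. Of 39 epidermal differentiation genes 37 were lower (median -7.30; -7.14, -7.29 and -7.23 within slides; adjusted p = 3.18e-28 and adjusted p = 0.00289 with an estimated correlation). The cornified envelope gene Lor was at -12.60 ± 0.44, Krt1 at -12.23 ± 0.29 and Krtdap at -11.97, and Dmkn (-12.65) and Mal (-11.79) were as low. Fam25c was at least 4249-fold, Krtap13 at least 2917-fold, Crct1 at least 2019-fold, Dynap at least 1539-fold and Acer1 at least 915-fold lower (adjusted p at most 6.33e-10). FGF response genes were higher in LG epithelium for 13 of 15 (Etv5 4.19 ± 0.23, Shisa2 4.09, Etv4 4.05; median 1.98, with 1.99, 2.35 and 1.64 within slides; adjusted p = 1.23e-06 and adjusted p = 0.0494 with an estimated correlation). Hedgehog response genes were lower for 6 of 9 (Gli1 -6.80, Ptch1 -2.81; adjusted p = 0.000432 and adjusted p = 0.027 with an estimated correlation). Hair placode and follicle genes were lower for 11 of 21 and higher for 1 (Lef1 -8.48, Dkk4 -7.35; adjusted p = 2.3e-05 and adjusted p = 0.00542 with an estimated correlation). Conjunctival and corneal genes were lower for 11 of 16 and higher for 2 (Psca -8.39, Krt4 -6.77; adjusted p = 0.00277 and adjusted p = 0.142 with an estimated correlation). Cell cycle genes were higher for 29 of 30 (Ccne1 2.38, Rrm2 1.88; adjusted p = 4.65e-09 and adjusted p = 0.0625 with an estimated correlation), and 18 of 24 genes of the secretory machinery of the endoplasmic reticulum were higher (Hyou1 1.74, Pdia4 1.30; adjusted p = 0.00382 and adjusted p = 0.521 with an estimated correlation).

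Sox10 (4.52 ± 0.29), Sox9 (2.65 ± 0.25) and Foxc1 (1.77 ± 0.32) were higher in LG than in eyelid epithelium, and Pax6 did not pass (0.98, adjusted p = 0.101). The highest genes were Col9a1 (9.67, but -0.03 with its other probe), Col2a1 (8.72), Alkal2 (7.70), the homeobox gene Dbx2 (7.61), the glutathione peroxidase gene Gpx2 (7.46), Crispld2 (169-fold), Spon1 (7.38), Wfdc18 (7.30) and the Wnt receptor gene Fzd9 (7.25), with Ush1c at least 129-fold higher. Pigment cell genes moved with the eyelid, with Dct at -10.32 and Pmel at -6.75, and 8 of 14 genes of their list lower and 1 higher, 2 higher when adjusted over the list alone (adjusted p = 0.000127 and adjusted p = 0.0496 with an estimated correlation). Muscle genes did too, 10 of 25 lower and 1 higher (Tnni2 -3.73; adjusted p = 0.0423 and adjusted p = 0.808 with an estimated correlation), although with slide as a block that list ended at adjusted p = 0.0543. There were 4442 genes higher and 2992 lower (5246 and 3490 with slide as a block), with a median over all genes of 0.10. At least 2-fold they were 1949 and 2071, and without the filter on dim probes 4344 and 4031. HG epithelium against eyelid epithelium gave 4339 and 2943 (5134 and 3436 with slide as a block; median 0.11), or 1903 and 1989 at least 2-fold. Its epidermal list was lower for 36 of 39 genes, 37 when adjusted over the list alone (Lor -12.48, Ly6d -11.98, Krt1 -11.97; median -7.03; adjusted p = 6.91e-29 and adjusted p = 0.00257 with an estimated correlation). Col9a1 (8.78, -0.30 with its other probe), Col2a1 (7.84), Dbx2 (7.57), Wfdc18 (7.31), Gata6 (7.30), Sox10 (3.87) and Sox9 (3.13) were higher there. Hedgehog genes were lower for 7 of 9 (Gli1 -6.06; adjusted p = 0.000471 and adjusted p = 0.0421 with an estimated correlation), and FGF response genes were higher for 13 of 15 and lower for 1 (Etv4 4.81; adjusted p = 1.18e-05 and adjusted p = 0.0635 with an estimated correlation). Endothelial genes moved with the HG epithelium, 11 of 17 higher, 12 when adjusted over the list alone (Flt1 2.24; adjusted p = 0.0025 and adjusted p = 0.73 with an estimated correlation).

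A set of 119 genes was at least 2-fold higher in LG epithelium than in LG mesenchyme, HG epithelium and eyelid epithelium alike. Independent lists of 2664, 313 and 1949 genes among 16324 would share 6.10, and the highest of 100 simulations with unchanged groups was 1. The 3 comparisons share the LG epithelium arrays, so part of the overlap may come from those arrays. The simulated groups did not differ at all, so their count does not show what chance gives where the other groups truly differ. Among those well above background on at least 1 array of each of the 4 groups, the smallest of the 3 differences was 4.25 for Crispld2, 3.76 for Alkal2, 3.44 for Lcn2, 2.63 for Rtn1 and 2.32 for Chil1. Lgsn, Fam163a, Rag1, Chrm3, Cldn22, Kcnmb1, Otor, Adcy8, Zpld2, Slc6a2, Htr5b, Pipox, Ceacam10, Ush1c and Aqp5 belonged to the set as well. These are among 40 of the 119 that were well above background on no array of at least 1 of the other 3 groups, so their sizes are uncertain. In the adult glands 42 of the 119 were higher in LG than in HG and 28 lower, whether or not they were well above background there. Ceacam10 and Htr5b kept the direction, whereas Chil1 (-7.01), Slc6a2 (-2.69), Crispld2 (-2.57), Cldn22 and Alkal2 were higher in adult HG. Of the set, 83 genes were shared with the set found without slide 1, 101 with quantile normalization and 72 with normexp background correction and quantile normalization together.

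**Figure D3:**
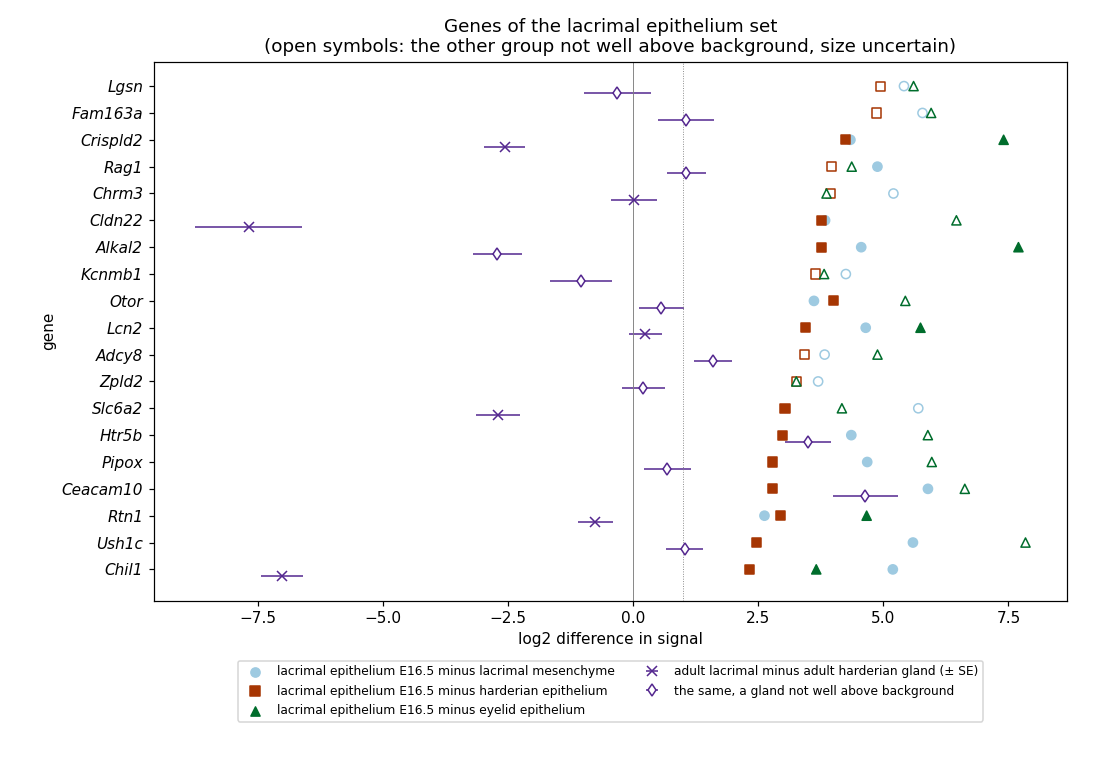
Log2 differences of high-ranking genes of the LG epithelium set: LG epithelium minus LG mesenchyme, minus HG epithelium and minus eyelid epithelium, and adult LG minus adult HG (± SE). Embryonic differences range from 2.32 for the smallest of Chil1 upward, while the adult difference is 4.64 for Ceacam10 and -7.68 for Cldn22.

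The 3 mesenchymes (3 arrays each) were compared to ask whether the connective tissue around each epithelium differs. Fgf10 did not pass between LG and HG mesenchyme, with means of 4.23 and 4.24 (adjusted p = 0.998), and exceeded the eyelid in both, by 3.27 ± 0.71 (adjusted p = 0.00161) and 3.28 ± 0.71 (adjusted p = 0.00214). LG mesenchyme had more Pantr1 (5.37 ± 0.83), the metalloprotease gene Adamts16 (5.35 ± 0.38, but 1.25 with its other probe), Pax1 (at least 19.5-fold), Col6a5 (at least 12.3-fold, but -0.35 with its other probe) and Mlc1 (at least 8.21-fold) than HG mesenchyme (adjusted p at most 0.000734). It had less of the peptide hormone gene Cck (-7.33 ± 0.41, adjusted p = 1.42e-09; -6.92, -7.50 and -7.56 within slides), Grp (at least 117-fold), the Wnt inhibitor gene Wif1 (at least 56.9-fold), the noradrenaline transporter gene Slc6a2 (at least 33.1-fold) and Sp5 (at least 30.1-fold). Cell cycle genes were higher in LG mesenchyme for 11 of 30, 18 when adjusted over the list alone (Ccne1 1.28, Rrm2 1.08, Mcm3 1.07; median 0.55, with 0.62, 0.58 and 0.55 within slides; adjusted p = 8.17e-10 and adjusted p = 0.135 with an estimated correlation). Pigment cell genes were higher in HG mesenchyme, with Tyrp1 at -6.07, Dct next, Mlana at -4.77 and Pmel at -4.61 (8 of 14 lower in LG and 1 higher; adjusted p = 1.41e-06 and adjusted p = 0.0514 with an estimated correlation). Of 25 muscle genes 4 were lower in LG mesenchyme and 1 higher, 11 and 1 when adjusted over the list alone, and the list missed the threshold (adjusted p = 0.0534). Myog was at least 12.7-fold and Actc1 (-5.38, adjusted p = 0.014) lower, but Myh2 higher (3.21, adjusted p = 0.0136). Actc1 missed the threshold without HG mesenchyme replicate 3 (adjusted p = 0.071) and Myh2 without LG mesenchyme replicate 3 (adjusted p = 0.0512). The neurofilament genes Nefl (3.68) and Nefm (2.92) and Prph (1.77) were the 3 of 12 neuronal genes higher in LG mesenchyme (adjusted p = 0.00977 and adjusted p = 0.487 with an estimated correlation). Epidermal genes were lower for 8 of 39, 9 when adjusted over the list alone, among them Calml3 (-3.59) and Krt1 (-3.05), beside the basal keratin gene Krt15 (-4.87; list adjusted p = 0.00607 and adjusted p = 0.737 with an estimated correlation). Foxc1 was lower in LG mesenchyme (-1.37, adjusted p = 0.00549). In total 1056 genes were higher and 1281 lower (1452 and 1875 with slide as a block), 607 and 773 without slide 1. The balance turned with normexp background correction and quantile normalization together (1605 and 1564) and was near level with quantile normalization alone (1321 and 1371).

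Both gland mesenchymes differed from eyelid mesenchyme in muscle and in Wnt response. Muscle genes were lower in the LG for 20 of 25 with 1 higher, 22 lower when adjusted over the list alone (Actc1 -10.45 ± 1.42, Myog at least 332-fold; adjusted p = 1.06e-12 and adjusted p = 0.168 with an estimated correlation). In the HG 21 were lower, 22 when adjusted over the list alone (adjusted p = 2.95e-13 and adjusted p = 0.233 with an estimated correlation). Wnt response genes were lower in the LG for 12 of 15 with 2 higher (Wif1 at least 536-fold, Dkk1 at least 146-fold, Lef1 at least 103-fold; adjusted p = 7.34e-08 and adjusted p = 0.0137 with an estimated correlation). In the HG 14 were lower (Dkk1 -5.15, Apcdd1 -4.05, Lef1 -3.92; adjusted p = 4.46e-12 and adjusted p = 0.00278 with an estimated correlation). Hair placode and follicle genes were lower for 16 of 21 in both, with 1 higher in the LG (adjusted p = 3.52e-10 and 2.95e-13; adjusted p = 0.000322 and 6.37e-05 with an estimated correlation). Epithelial and epidermal markers moved with the eyelid mesenchyme in the same comparisons. Of 45 epithelial genes 34 were lower in each gland mesenchyme, 35 when adjusted over the list alone (adjusted p = 6.67e-15 and 1.96e-17; adjusted p = 0.161 and 0.167 with an estimated correlation). In the HG the slides differed, with medians of -1.20, -0.69 and -3.68. Krt15 was at -9.09 and Krt5 at -6.18 in LG against eyelid mesenchyme, and epidermal genes were lower for 27 of 39 in the LG with 1 higher, 30 and 2 when adjusted over the list alone (adjusted p = 1.26e-16 and adjusted p = 0.0137 with an estimated correlation). Npy2r was higher in both (8.02 ± 0.59 and 7.75), as were Brinp3 (7.01 in each) and the crystallin gene Cryge (at least 113-fold in the LG and 26.0-fold in the HG). In the LG Ambn (6.93) and Folh1 (at least 69.6-fold) were higher, and Tceal7 (at least 289-fold) and Sln (at least 217-fold) lower. In the HG Klhl1 (7.54) and Wdr72 (at least 30.9-fold, 0.34 with its other probe) were higher, and Pax1 (at least 381-fold), Krtap13 (at least 37.2-fold), Pantr1 (-9.13), Calm4 (-7.46) and Dmkn (169-fold) lower. Dmkn and Krtap13 were also far lower in LG than in eyelid epithelium, so epithelium carried over into eyelid mesenchyme may be their source, which was not tested. The LG had 2533 genes higher and 2558 lower (3426 and 3163 with slide as a block), the HG 1816 and 1838 (2634 and 2237 with slide as a block). At least 2-fold the balance was toward lower, with 993 and 1700 in the LG and 815 and 1389 in the HG, whereas among probes well above background on all 23 arrays it was toward higher, with 1908 and 1381 in the LG and 1232 and 782 in the HG.

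Adult LG (2 arrays) and adult HG (3 arrays) parted along their secretions. Of 27 lacrimal secretory genes 18 were higher in adult LG and 5 lower, with a median of 4.54 (adjusted p = 2.73e-05 and adjusted p = 0.0722 with an estimated correlation). Lactoperoxidase, Lpo, was higher 2051-fold (adjusted p = 2.81e-13; 10.28 and 10.41 within slides 2 and 3; adjusted p = 4.4e-12 with slide as a block). The lipocalin gene Lcn11 (11.97 ± 1.35), the nuclease gene Dnase1 (11.01) and the secretoglobin gene Scgb1b24 (9.98) were others. Of 24 genes of the endoplasmic reticulum machinery 21 were higher (Derl3 7.02, Sdf2l1 4.81, Xbp1 3.26; adjusted p = 6.43e-12 and adjusted p = 0.0722 with an estimated correlation), and so was the acinar factor gene Bhlha15 (8.81 ± 0.47). Lipid synthesis marked the HG, with 32 of 42 genes lower in adult LG and 5 higher. The fatty acid elongase gene Elovl3 was at least 1682-fold and the acyltransferase gene Dgat2l6 at least 1245-fold lower, Mogat1 was at -10.70 and Elovl5 at -9.35 (median -4.24, with -4.59 and -4.57 within slides; adjusted p = 2.42e-11 and adjusted p = 0.0722 with an estimated correlation). Porphyrin synthesis, for which the rodent HG is known, was lower for 12 of 14 genes and higher for 1 (the transporter gene Abcg2 -6.85, Alad -3.14, Urod -3.07; adjusted p = 0.00042 and adjusted p = 0.234 with an estimated correlation).

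Six2 (6.31), Foxc1 (1.60), Sox9 (1.24) and Fgfr2 (0.99) were higher in adult LG, whereas Sox10 was lower (-2.94) and Pax6 did not pass (0.74, adjusted p = 0.249). The gland regulators of which these are members were higher for 12 of 27 and lower for 6 (adjusted p = 0.0289 and adjusted p = 0.543 with an estimated correlation). The highest genes also included Fgg (11.95), Olfr1348 (11.45), Sval2 (11.05), Scgb2b19 (10.81), the urinary protein genes Mup20 (10.69) and Mup4 (10.67), and Slc2a5 (at least 1148-fold). The lowest included Psapl1 (-11.58), Aadacl4fm1 (-11.38), Bpifa6 (-11.35 ± 1.94), the neuropeptide gene Cartpt (-11.15), Cyp4a32 (at least 870-fold), S100a8 (at least 826-fold), Fcmr (at least 597-fold) and the sphingolipid enzyme gene Sptlc3 (at least 2095-fold, -6.80 with its other probe). Connective tissue and pigment cell markers moved with adult HG. Mesenchymal genes were lower in adult LG for 28 of 35 and higher for 1, 29 lower when adjusted over the list alone (median -1.35; adjusted p = 0.00036 and adjusted p = 0.615 with an estimated correlation), and endothelial genes for 12 of 17 with 1 higher (adjusted p = 0.0178 and adjusted p = 0.615 with an estimated correlation). Dct was at least 261-fold lower. Adult HG replicate 1 stood apart in muscle genes, whose median was 0.23 on that array against -3.07 and -4.90 on the others; 9095 genes were called without it. In total 3660 genes were higher and 5420 lower (4211 and 5986 with slide as a block), or 40.3 percent higher, and the median over all genes was -0.13. Without the filter on dim probes the balance turned, with 5880 higher and 5392 lower, or 52.2 percent. Median scaling gave 1901 and 4915, or 27.9 percent, and a fit of the adult groups alone 1656 and 2711. Arrays of an adult group correlated less with each other (0.971 in LG, 0.959 in HG) than those of embryonic groups (0.985 to 0.990). The spread taken over all 8 groups may therefore be too small for adult glands, and so may their SE and p-values. A fit of fewer arrays also has less power.

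Adult glands were set against the embryonic epithelium of the same gland, although a whole gland and a separated epithelium differ in composition as well as age. The Y-linked genes Ddx3y and Eif2s3y were also well above background on every embryonic array and on no adult array, so sex-linked signal differed with age too, and none of these can be told apart. Cell cycle genes were lower in adult LG for 29 of 30 (Ccnb1 -8.40, Cenpe -8.35, Birc5 -7.51; median -5.81; adjusted p = 1.72e-14 and adjusted p = 0.0368 with an estimated correlation) and in adult HG for all 30 (Top2a -7.69, Bub1 at least 75.5-fold; median -5.50, with -6.36, -5.12 and -5.75 within slides; adjusted p = 4.18e-16 and adjusted p = 0.0493 with an estimated correlation). Lacrimal secretory genes were higher in adult LG for 24 of 27 and lower for 2 (median 6.60, with 6.46 and 5.49 within slides; adjusted p = 5.95e-09 and adjusted p = 0.0266 with an estimated correlation). Lcn11 was at least 92245-fold, Scgb2b7 at least 83849-fold, Sval2 at least 67151-fold, Scgb2b24 at least 65131-fold and Mucl2 at least 57997-fold higher. In adult HG lipid synthesis genes were higher for 33 of 42 and lower for 5 (Cidea 12.04, Acsbg1 at least 5951-fold; adjusted p = 8.32e-10 and adjusted p = 0.0675 with an estimated correlation). Genes of the porphyrin synthesis list were higher there for 13 of 14 (adjusted p = 7.97e-06 and adjusted p = 0.0765 with an estimated correlation). Among them were Tspo (5.27), Hmox1 (4.40) and Alas1 (4.23), of which Hmox1 encodes an enzyme that degrades heme and not one of synthesis. Wnt response genes were lower in adult HG for 14 of 15 (median -4.50, adjusted p = 0.00012 and adjusted p = 0.0765 with an estimated correlation). Sptlc3 was at least 6444-fold, Elovl3 at least 5172-fold and Dgat2l6 at least 3830-fold higher, and Bpifa6 and Cartpt were both at 14.23.

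Immune genes were higher in adult LG for 23 of 25 (H2-Aa at least 278-fold, Jchain 7.26; adjusted p = 2.56e-07 and adjusted p = 0.478 with an estimated correlation) and in adult HG for 21 (medians 4.23, 2.54 and 1.37 within slides; adjusted p = 1.97e-05 and adjusted p = 0.41 with an estimated correlation). Adipocyte genes were higher in adult HG for 8 of 10 and lower for 1 (adjusted p = 0.0138 and adjusted p = 0.194 with an estimated correlation). In adult LG 6 were higher and 1 lower (adjusted p = 0.0396 and adjusted p = 0.413 with an estimated correlation), a call that ended with slide as a block (adjusted p = 0.0706). Endothelial genes were higher in adult HG for 13 of 17, 14 when adjusted over the list alone (medians 3.19, 1.12 and 0.67 within slides; adjusted p = 0.0129 and adjusted p = 0.632 with an estimated correlation). Col2a1 was at least 868-fold lower in adult LG and at least 931-fold lower in adult HG, and Col9a1 was lower in the LG by a probe not well above background there, but at 1.44 with its other probe. In the LG Fabp7 (at least 254-fold) and H2bu2 (at least 133-fold) were lower, and in the HG Bex4 (at least 586-fold) and Sp5 (at least 142-fold). Sox10 was lower in adult LG (-3.79) and did not pass in the HG (-0.19, adjusted p = 0.567). Adult LG had 5091 genes higher and 6312 lower (5612 and 6712 with slide as a block), or 3228 and 6897 with median scaling. Without the filter on dim probes the balance turned, with 8738 and 6290. Adult HG had 5622 and 5807 (6192 and 6161 with slide as a block), or 7438 and 5775 without that filter. Probes near background may read too high after scaling on the dimmer adult arrays. The turns without the filter are thus no evidence of more transcripts higher in adult glands.

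The signed difference, LG minus HG, was called as changed between embryonic epithelium and whole adult glands for 7380 genes. It shifted toward the LG for 2952 and toward the HG for 4428 (3517 and 5200 with slide as a block, median over all genes -0.15). A shift toward the HG can be a difference that reversed, as for Mogat1, higher in LG epithelium (1.67) but lower in adult LG. Age, tissue composition and sex-linked signal cannot be told apart in these shifts. Median scaling gave 1474 and 3498, whereas without the filter on dim probes the balance turned, with 5034 toward the LG and 4372 toward the HG. That turn has the same limit of probes near background on the dim adult LG arrays. Serpinb11 (13.20), Lcn11 (12.96 ± 1.81), Slc2a5 (12.21) and Sval2 (12.14) gained most in the LG, and Mogat1 (-12.37), Elovl3 (-12.09) and Cyp4a32 (-11.76) in the HG. Sox10 (-3.59 ± 0.43, adjusted p = 2.19e-06), Sox9 (1.72) and Fgfr2 (0.78) were among the genes whose LG minus HG difference changed between embryonic epithelium and whole adult glands.

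**Figure D4:**
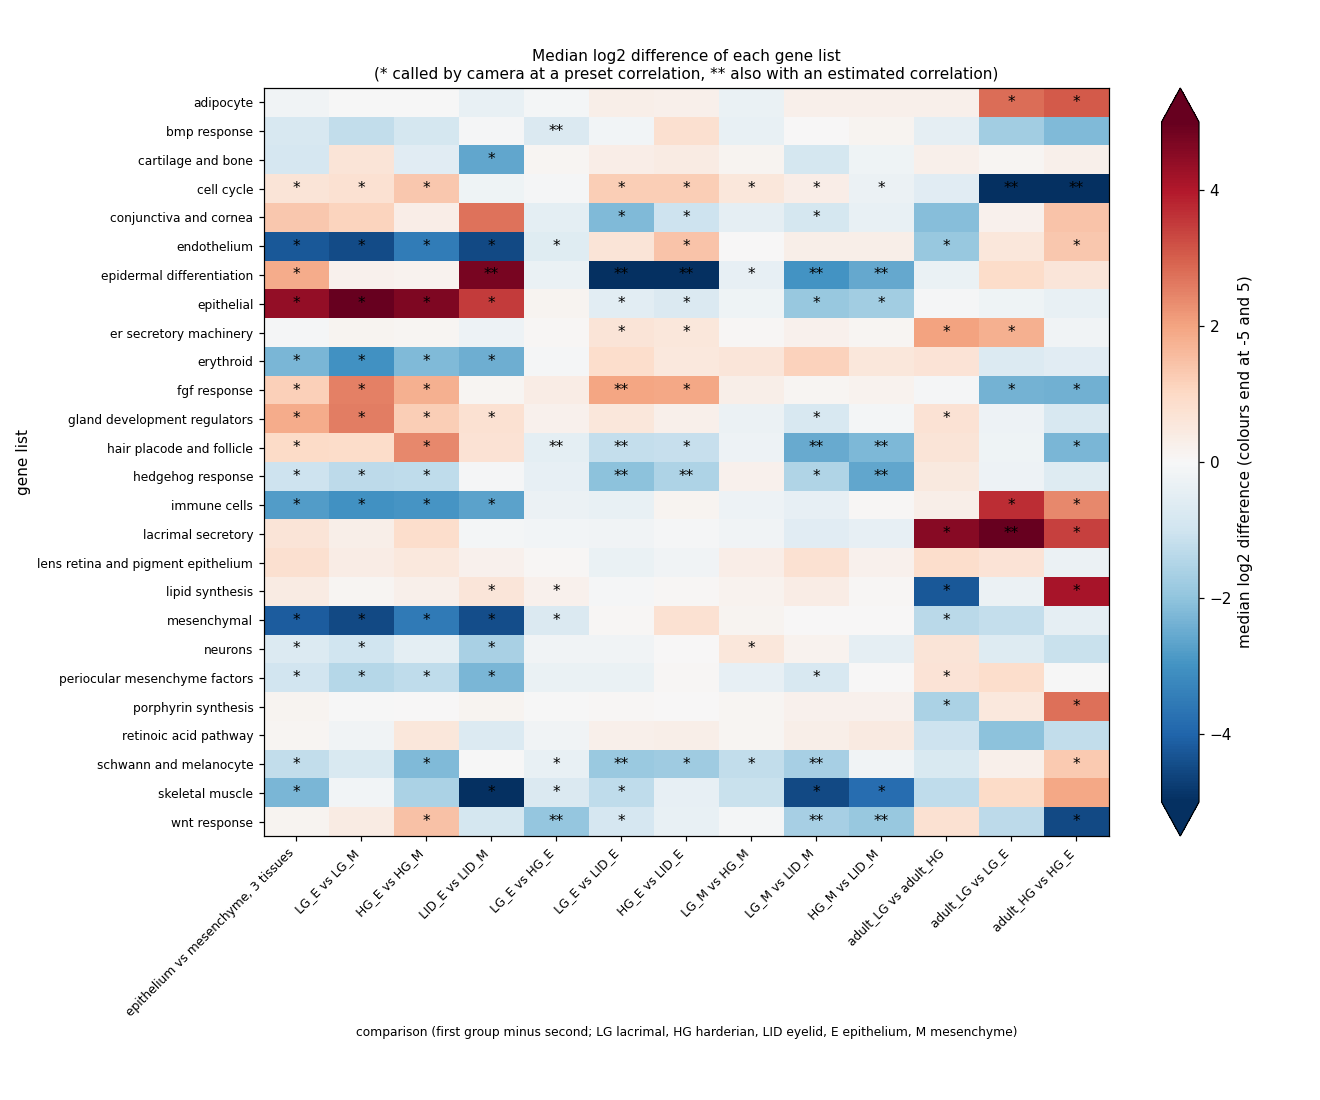
Median log2 difference of 26 gene lists (vertical) in 13 comparisons (horizontal), colour scale ending at -5 and 5; 1 asterisk marks lists called with the preset correlation and 2 asterisks those also called with an estimated correlation. Of 338 tests 127 were called, 22 of them with an estimated correlation, and the epidermal list is lowest at -7.30 in LG against eyelid epithelium.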

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

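In the weighing below, the test of Wnt response genes between HG epithelium and HG mesenchyme was chosen only after the result was seen. A difference between groups drew attention in each of the results that follow. From embryonic epithelium to whole adult glands, LG minus HG shifted toward the LG for 2952 genes and toward the HG for 4428. Age, tissue composition and sex-linked signal cannot be told apart in this shift. Serpinb11 (13.20), Lcn11 (12.96), Slc2a5 (12.21), Sval2 (12.14) and Scgb1b24 (11.83) changed most toward the LG, and Mogat1 (-12.37), Elovl3 (-12.09), Cyp4a32 (-11.76), Sptlc3 (-11.51) and Cartpt (-11.44) most toward the HG. The regulator genes Fgfr2 (0.78), Sox9 (1.72) and Sox10 (-3.59) also passed that test. Each of the 10 genes named for the largest changes was not well above background on every array of at least 1 of the 4 groups compared, so the sizes of these fitted differences are uncertain.

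The difference between epithelium and mesenchyme depended on the tissue for 6905 genes. The F values of the largest were 363 for Sprr2d, 341 for Limch1, 318 for Lmo7, 312 for Dnase1l2 and 308 for Sbsn. Sox10 (81.6), Foxc1 (19.7), Sox9 (15.8), Pax6 (8.03) and Fgfr2 (5.49) passed as well. In Dnase1l2 and Sbsn the eyelid epithelium exceeded its mesenchyme by 3.95 and 4.74, against -0.15 and -0.90 in the LG. Sprr2d was at least 25.1-fold higher in eyelid epithelium and not well above background in either LG compartment.

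More called genes were lower than higher in adult LG than in adult HG, with 40.3 percent higher. Distortion of the 75th percentile by a few very bright secretory transcripts would bring the share near balance under quantile normalization, but it stayed at 41.0 percent. Loss of low transcripts on the dimmer adult LG arrays would do the same among genes well above background on all 5 adult arrays, but among 11374 such genes, 6572 of them called, 37.8 percent were higher. Median scaling lowered the share to 27.9 percent, and without the filter on dim probes it rose to 52.2 percent. The excess of lower genes therefore depends on the scaling for its size and was seen only among genes that pass the filter. In no group were the probes that the filter removes well above background on every array, so their direction is uncertain. Ddx3y and Eif2s3y, well above background on no adult array, still read higher in adult LG (-4.99 and -5.22) than in adult HG (-6.10 and -6.29). The turn without the filter is thus no evidence of more transcripts higher in adult LG. A difference in cell composition or transcription between the glands stays open, untested.

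Col2a1 and Col9a1, collagen genes known from cartilage, were far higher in LG epithelium than in eyelid epithelium. Cartilage cells in the preparation would raise the other cartilage genes too, yet the median difference of 5 others was -0.094, with Col9a2 at 4.60 and Comp also higher but Acan at -0.11, Col11a2 at -0.09 and Hapln1 at -1.75. Mesenchyme carried over would leave the LG epithelium no higher than its mesenchyme, yet Col2a1 and Col9a1 averaged 5.88 (SE 0.441) above it, Col9a1 by only 1 of its 2 probes. Expression of these genes by the gland epithelium itself, where Sox9 (2.41) and Sox10 (5.18) were also higher than in LG mesenchyme, may therefore be a hypothesis to follow, with the test value 5.88 found and tested on the same arrays. The pattern was not particular to the LG, since HG epithelium also exceeded HG mesenchyme in Col2a1 (5.09), Col9a1 (5.28), Sox9 (2.51) and Sox10 (3.84). What remains open is the Col9a1 probe that did not differ.

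Wnt response genes were lower in LG than in HG epithelium, while mesenchymal markers were also lower. More mesenchyme in the HG preparation would need the 8 members concerned to be higher in HG mesenchyme than in HG epithelium, yet their median was 2.16 higher in the epithelium, with 6 called higher, Wif1 called lower (-1.52) and Nkd1 near level (0.12, adjusted p = 0.827). For Wif1 and Nkd1 carry-over of mesenchyme stays open. The 8 members were chosen as lower in LG than in HG epithelium, so the same HG epithelium arrays chose and tested them. Carry-over of eyelid epithelium was not tested. Lef1 (3.07 against 0.26), Apcdd1 (1.68 against -0.34), Wif1 and Axin2 were higher on average in eyelid than in HG epithelium. Lgr5, Nkd1, Sp5 and Tcf7 were lower there. Whether Wnt signalling itself differs between both gland epithelia was not tested and stays open. Slide 1, where the mesenchymal markers were level (0.02), still gave a Wnt median of -1.61.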

How the results depend on the processing

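Each gene result named in the text or its tables was recomputed under each setting that applied to it and with each array left out. Of these recomputed values 27427 kept direction and side of the threshold, 810 missed the threshold and 5 reversed; for list calls the numbers were 4327, 203 and 1. The cause was not tested except where the setting shows it. Median scaling lowered the number of called genes in LG against HG epithelium (630), LG against HG mesenchyme (1235), LG and HG against eyelid mesenchyme (2771 and 2204) and for the F test (3953). Requiring probes well above background on all 23 arrays tests fewer genes and gave 5320 for eyelid epithelium against mesenchyme, 516 for LG against HG epithelium, 1252 for LG against HG mesenchyme, 3289 and 2014 for LG and HG against eyelid mesenchyme, 51 for the LG epithelium set and 75 list calls. Without slide 1, and so with fewer arrays, LG against HG mesenchyme gave 1380 and HG against eyelid mesenchyme 2432. A fit of only the compared groups gave 4309 for LG against HG mesenchyme and 4367 for adult LG against adult HG. The 2-fold threshold by construction left 5378 genes for epithelium against mesenchyme over 3 tissues, 5843 in the LG, 5988 in the HG, 5248 in the eyelid, 4020 and 3892 for LG and HG against eyelid epithelium, 1367 for LG against HG mesenchyme, and 2693 and 2204 for LG and HG against eyelid mesenchyme, and dropping it gave an LG epithelium set of 210. With an estimated correlation 22 of 127 list calls held. Some alternatives were chosen after seeing the data: keeping probes without a symbol, and leaving out genes at least 4-fold higher in the other compartment, which gave 660 for LG against HG epithelium.

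Among the reversed results were Hoxc13 in adult LG against HG (-0.063) and Foxf2 (-0.13) and Chrng (-0.094) in adult against embryonic LG with normexp and quantile normalization, and Foxd3 in the latter with quantile normalization (-0.21), all without passing. The periocular list in LG epithelium against mesenchyme reversed with the filter on all 23 arrays (adjusted p = 0.960, limma's camera). With 1 array left out, called genes ran from 743 to 954 in LG against HG epithelium (main 1037), 1628 to 1844 in LG against HG mesenchyme (main 2337), 7805 to 9095 in adult LG against HG (main 9080), 91 to 121 for the LG epithelium set and 121 to 131 for list calls. They ran from 11217 to 11410 for epithelium against mesenchyme over 3 tissues, 8609 to 8983 in the LG, 8545 to 9027 in the HG, 7517 to 7766 in the eyelid, 6363 to 6857 and 6261 to 6849 for LG and HG against eyelid epithelium, 3886 to 4470 and 2645 to 3088 for LG and HG against eyelid mesenchyme, 10074 to 11165 and 10679 to 11432 for adult against embryonic LG and HG, 6622 to 7734 for the difference by age and 6069 to 6637 for the F test. No count moved by more than 1.5 times with an array left out. Where an adult LG array is left out, the lone remaining array is assumed to vary like the other groups. The replicate block, which respects the pairing, gave 572 higher and 615 lower in LG against HG epithelium and shared 117 genes with the LG epithelium set. With this block no count moved by over 1.5 times, 1385 named gene results held and 4 missed the threshold, and 124 list calls held and 3 missed it. Signal over background limits what can be said of dim transcripts, most of all in adult LG.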

Other observations

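The list of 25 immune genes did not pass between LG and HG mesenchyme (3 lower, adjusted p = 0.373, limma's camera), but a few of its members differed. The B-lineage genes Mzb1 and Pou2af1 were higher in HG than in LG mesenchyme (LG minus HG -3.17 ± 0.66 and -3.04 ± 0.99; adjusted p = 0.00241 and 0.0477, limma). They were higher there than in eyelid mesenchyme too (Mzb1 2.44, Pou2af1 3.48). The calprotectin genes S100a8 (-2.95) and S100a9 (-3.24), members of the conjunctival list, were lower in LG than in HG mesenchyme, and the lacrimal secretory gene Ltf was at -3.02. In the adult Pou2af1 stood the other way, higher in LG (4.80, adjusted p = 0.00127). The endothelial gene Vwf was higher in HG than in LG mesenchyme (-3.37).

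Genes of retinoic acid handling, of which 13 were measured, did not pass as a list in any comparison. In adult LG against HG 1 was higher and 8 lower (Crabp2 2.52, Aldh1a1 -3.23, Rdh10 -2.04; adjusted p = 0.0944). The synthesizing enzyme gene Aldh1a2 (3.90) and the retinol receptor gene Stra6 (3.06) were higher and the degrading enzyme gene Cyp26b1 (-2.11) lower in LG than in eyelid mesenchyme, as Stra6 (6.07) and Aldh1a3 (3.80) were higher in LG than in eyelid epithelium. Lens, retina and pigment epithelium genes (8 measured) were not called in any comparison either, with 4 higher and 1 lower in LG against eyelid mesenchyme (Cryga 2.82, Rlbp1 1.99, Crygs 1.89, Cryab -2.65; adjusted p = 0.341). Sex-linked genes were too few for a test. Ddx3y and Eif2s3y, both on the Y chromosome, were well above background on every embryonic array and on none of the 5 adult arrays, with adult means of -6.10 and -6.29 in HG and -4.99 and -5.22 in LG, while Xist was well above background on all. The embryonic arrays therefore held both sex-linked signals, whereas the adult arrays held Xist without the Y-linked signal, as female tissue would. The sex of the mice was not otherwise analysed here, so whether the adult differences between LG and HG hold in males is not known.

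A hypothesis chosen only after the result was seen, and tested on the same arrays, was that genes of the LG epithelium set are higher in adult LG too. Of the 119 set genes 35.3 percent were called higher in adult LG than in adult HG, against 22.3 percent of the 16205 other genes (Fisher's exact test, two-sided, p = 0.00128), and 23.5 against 33.3 percent were called lower (Fisher's exact test, p = 0.0245). Part of the embryonic difference may last into the adult gland (Fisher's exact test, p = 0.00128), but 28 set genes were lower there. Genes are not independent, and a whole gland holds other cells than its epithelium. Set genes not well above background in the adult glands were not left out. Ddx3y and Eif2s3y, well above background on no adult array, read higher in adult LG (-4.99 and -5.22) than in adult HG (-6.10 and -6.29). Absent genes could thus be called higher in adult LG, and the test cannot tell this from lasting expression.

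Other splits of the same arrays were counted for each result. For epithelium against mesenchyme over 3 tissues 1 of 100 splits, the real one, called as many genes (11527, highest other 9027). The high counts of other splits show that the arrays have a strong structure of tissue and compartment. The real split alone also gave its count for the F test (1 of 100, 6905 against 3701 at most) and the LG epithelium set (1 of 100, 119 against 52 at most). Other splits mix unlike tissues or compartments within a group, which widens the spread. These shares therefore show only that the arrays are not interchangeable, and cannot tell how many of the genes were called by chance. The number of list calls in embryonic comparisons did not stand out, since 9 of 40 splits gave as many (102, highest other 109). In comparisons of 3 arrays against 3 the 10 splits are too few for a share under 0.05, and the real split alone, 1 of 10, gave its count. The real and highest other counts were 9569 and 0 for LG epithelium against mesenchyme, 9447 and 0 for the HG, 8354 and 1 for the eyelid, 1037 and 5 for LG against HG epithelium, 7434 and 1 for LG against eyelid epithelium, and 7282 and 7 for HG against eyelid epithelium. They were 2337 and 1 for LG against HG mesenchyme, 5091 and 1 for LG against eyelid mesenchyme, 3654 and 0 for HG against eyelid mesenchyme, and 11429 and 25 for adult against embryonic HG. Splits of the embryonic arrays that part every numbered pair, as the real ones do, gave at most 7.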
